A study of Escherichia coli with 4 samples.

How the data were processed

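Transcript levels of Escherichia coli MG1655, a laboratory K-12 strain, were compared with those of an otherwise matching strain carrying a Tn5 transposon in norR. NorR is a transcription factor that senses nitric oxide. Both strains were grown anaerobically in chemostats (continuous culture at a dilution rate of 0.1 per hour, working volume 1 litre) on 54 mM glycerol with 50 mM fumarate as electron acceptor, under nitrogen at 0.2 litres per minute. RNA was taken 5 min after adding 10 µM each of NOC-5 and NOC-7, compounds that release nitric oxide. Each strain was grown in 2 separate runs. The RNA of the 2 strains from a run was hybridised together on 1 array and again on a second array with the dyes exchanged, which gives 4 two-colour arrays. The arrays are called 1-first, 1-swap, 2-first and 2-swap, where the number is the run. On the first arrays the mutant carried Cy5 and on the swapped arrays it carried Cy3, per the labels. The run was the replicate (n = 2), and the dye swap was treated as technical. There were no arrays without nitric oxide among the samples used here.

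The authors deposited 1 processed signed log ratio per array feature, which was read as a log2 ratio because the base is not stated. The scanner, background correction, normalization and rule for missing values are not given in the sources used here. The column medians were -0.05, -0.03, -0.02 and -0.07 in the order of arrays given above. The direction is not stated either. In run 1, norV (-5.69 and -4.21) and norW (-4.63 and -5.30) keep their sign from 1-first to 1-swap, so 1-swap had already been turned. Neither gene has a value on 2-swap. That array is taken as turned because flagellar and chemotaxis genes, a list fixed beforehand, averaged 1.46 on 2-first and 0.47 on 2-swap. The genes aroF and flgB keep their sign too, but were chosen for 1 sign on all 4 arrays. Some other genes do not, such as metE at 0.62 on 2-first and -3.02 on 2-swap. Mutant over wild type is the likely direction, because norV and norW, the operon that NorR activates, are negative. If the convention were the opposite, every sign below would turn together. Intensities were not used here. The small number of arrays, from 2 runs, limits the precision.

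Of the 4608 features, 4087 have 1 gene symbol, 0 have several and 521 have none. Symbols were updated for 197 features through the gene identifier, using the NCBI RefSeq gene table of strain MG1655, in which 4086 of the named features were found. No coordinates are given, because no genome build is named. Features of one gene were averaged (49 genes have 2 or more). A value was present on all 4 arrays for 1332 features, on 3 for 1364, on 2 for 1072, on 1 for 643 and on 0 for 197. Each array was centred on its median, the arrays of a run were averaged, and genes with a value on all 4 arrays were tested, which left 1269 genes.

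Run means were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 17 gene lists were tested with camera of limma at a preset correlation of 0.01 where at least 3 members were measured, with adjustment over the lists tested. A second rule counted genes whose mean was at least 2-fold from equality with 1 sign on all 4 arrays. The same count was made for sign patterns that follow the dye, the run or the run by dye. It measures how often such patterns arise without a strain effect common to both runs. The run pattern can still hold strain differences of opposite sign in the 2 runs. The genes named are norR, norV and norW, then up to 10 highest and 10 lowest genes past the threshold with 1 sign on all 4 arrays. Where too few passed, the places were filled with genes at least 2-fold apart with 1 sign on all 4 arrays. Up to 4 measured members of each list with the largest mean follow. The gene lists, this rule, the tests and most alternatives were fixed before the data were examined.

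The procedure was tested on simulated data with the 1269 genes, 2 runs and spread of this comparison. Over 50 draws with 200 changed genes, limma recovered 31.4% of genes changed by 1 on the log2 scale, 93.9% of those changed by 2 and 99.3% of those changed by 3, and 6.49% of calls were false. The adjustment is stricter where fewer genes change, so these shares do not give the power of the real fit. There flgB, at 2.15, did not pass. With no gene changed, 35.0% of 200 draws still gave at least 1 call, where the threshold promises about 5%. When the true prior of the spread was supplied, this share was 4.50%. The excess therefore comes from estimating that prior with 1 residual degree of freedom per gene: its degrees of freedom were 3.54 at the 5th percentile of draws and infinite in 42 draws, 39 of which gave a call. For the 3074 genes with a value on at least 1 array of each run, 41.5% of draws with no changed gene gave a call, but only 2 of the 63 draws whose estimated prior had no more degrees of freedom than in the real data (7.76). The true prior is unknown, so single calls from these 2 runs are less secure than the threshold implies. A list of 10 genes shifted by 1 was called in 100% of 100 draws, and unshifted lists were called at 0.08 per draw, with genes simulated as independent.

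Alternatives were values without centring, arrays scaled to equal spread, the wider gene filter just named, each array or run left out, all 4 arrays in 1 fit (with the run as a random block, or as independent with and without a dye term), robust eBayes, single features, other thresholds, and camera with an estimated correlation or fry for lists. Centring each of the 16 print blocks of an array on its own median, and camera on 4 arrays with an estimated correlation, were added after seeing the data, as were an estimated correlation combined with print-block centring (with or without the wider filter) or with an array left out, and 2-fold counts with an array left out over the same 1269 genes.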

Results

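The data comprised 4 two-colour arrays of anaerobic E. coli sampled 5 min after nitric oxide release began, each setting a norR mutant against the wild type. They covered 2 chemostat runs with 1 dye-swap pair each. The arrays held values for 3169 (1-first), 3240 (1-swap), 2490 (2-first) and 3308 (2-swap) of 4608 features. Values are log2 ratios, in the likely direction of mutant over wild type, and errors are SDs of the 2 run means (n = 2). The direction rests on norV and norW alone, taken to be lower without their activator, and the log base is itself an assumption. The comparison asks which transcripts depend on NorR when nitric oxide is present.

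The norVW operon, which encodes the nitric oxide reductase flavorubredoxin and its redox partner and is activated by NorR, had very large ratios. Since these genes set the direction, the size of their difference is measured here and not its sign. The lowest value of the whole array was that of norV on 1-first and that of norW on 1-swap and 2-first. For norV, the values were -5.69 on 1-first and -4.21 on 1-swap, and run 2 gave none. For norW, they were -4.63, -5.30 and -2.93 on 1-first, 1-swap and 2-first, with a mean of -3.95 ± 1.44, a 15.5-fold difference. norR itself had a value of 1.34 on 1-swap and -0.23 on 2-first, which differ by more than their mean of 0.55. A transposon need not remove the part of the transcript that a feature detects, and its place relative to the feature is not given in the sources used here, so norR does not check the labels. None of the 3 genes had values on all 4 arrays, so none entered the main test. Among 3074 genes with at least 1 array of each run, norW passed in limma (adjusted p = 0.0369), but not after print-block centring (adjusted p = 0.673, mean -3.82). The value was negative on 3 of 3 arrays. norW also passed without 2-swap, where it has no value, in a fit whose prior had infinite degrees of freedom. Of simulated tables of this size without any change, 41.5% gave at least 1 call, so the threshold is looser than stated. Among the 63 such tables with a prior of no more degrees of freedom than the real fit, 2 did. The true prior is unknown.

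Flagellar and chemotaxis genes were higher in the mutant as a list. All 10 members measured on all 4 arrays had a positive mean in both runs. The list mean was 1.19, from 1.42 in run 1 and 0.96 in run 2 (camera adjusted p = 1.63e-13 at the preset correlation). That setting takes genes as nearly independent, so its p measures spread over genes and not over the 2 runs. Where the genes of a list vary together, such a p is too small, here and below. The call was lost with an estimated correlation (adjusted p = 0.917 on the run means and 0.866 on the 4 arrays with a dye term) and with fry (adjusted p = 0.780). Fry and camera with an estimated correlation rest on few residual degrees of freedom here, so they could hardly call any list. Every list had an adjusted p of 0.917 with an estimated correlation on the run means. Losing a call in this way therefore decides little, here and below. Run 2 alone, over the members with both its arrays, gave 0.75. Among the 10, flgB of the basal-body rod was at 2.15 ± 0.07, although its arrays ranged from 0.81 on 2-swap to 3.38 on 2-first. Leaving out 2-first gave flgB 1.503 and leaving out 2-swap 2.79. Further members were flgI of the P ring at 1.40 ± 0.13, and flhD, part of the master regulator of flagellar synthesis, at 1.33 ± 0.04. The flagellin gene fliC averaged 2.28 ± 1.20, with -0.23 on 2-swap against 2.72 to 3.54 on the others. Of the 10, 0 passed over all genes and 7 passed when adjusted over the list alone. With the wider gene filter, 35 of 41 members were higher in both runs and 0 were lower in both.

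**Figure D1:**
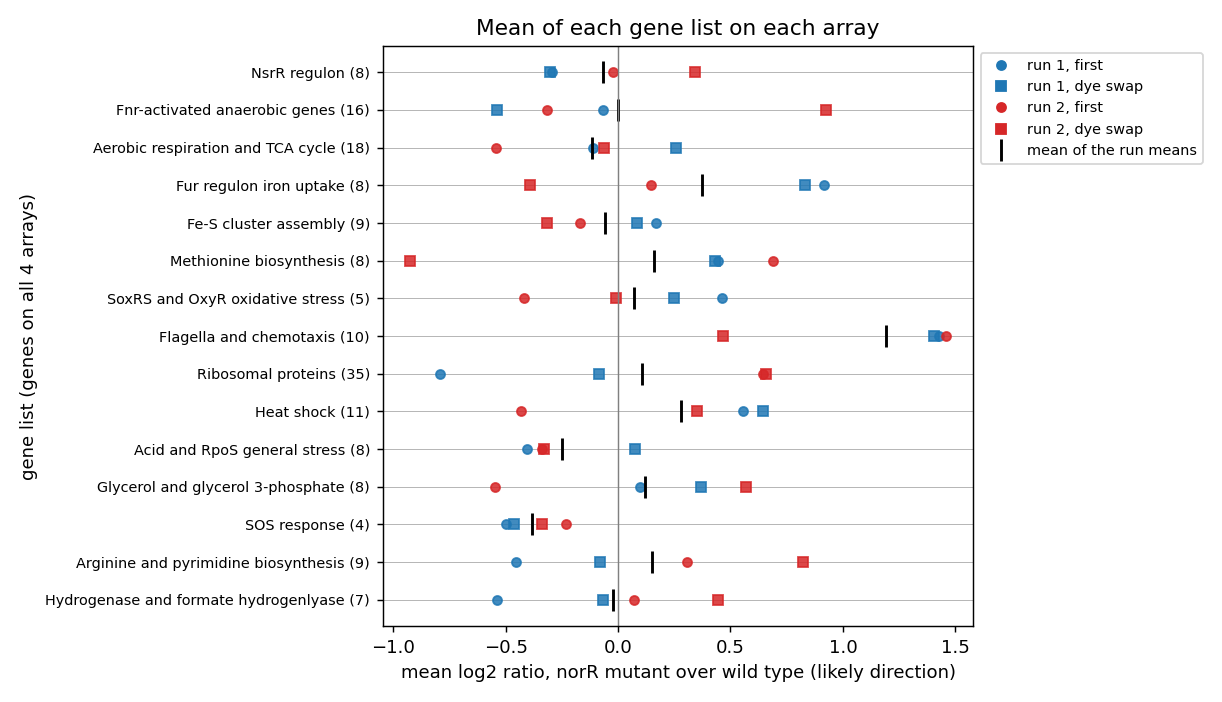
Mean log2 ratio (horizontal axis) of each gene list, with the number of genes measured on all 4 arrays, on each array (points) and as the mean of the run means (black bars). Flagella and chemotaxis lies at 1.43, 1.41, 1.46 and 0.47, while most other lists have arrays on both sides of 0.

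No single gene passed in the main test. Of 1269 genes, limma called 0 (smallest adjusted p = 0.206, for flgB), and 49 had an unadjusted p under 0.05 against 63.5 expected by chance. All 4 arrays in 1 fit, with the run as a random block or as independent arrays with or without a dye term, also called 0. The wider filter called 2, norW and tar, the aspartate chemoreceptor gene, which lay at 3.63 on 1-swap and 3.70 on 2-first (adjusted p = 0.00877) and is named here after its values were seen. In 29.5% of simulated tables without any change, the smallest adjusted p was as low. Among the 63 such tables with a prior of no more degrees of freedom than the real fit (7.76), 2 gave a call. The true prior is unknown. Print-block centring gave tar an adjusted p of 0.104, with its mean at 3.75, in a fit whose prior had 4.20 degrees of freedom. Without 2-swap 11 genes passed. They were norW, the flagellar or chemotaxis genes flgB, flgF, flgI, fliC, fliL and cheY, and aroF, ddpF, fimA and glpF. Without 1-swap 2 did, flgB and fliC. In both cases limma's estimated prior had infinite degrees of freedom, and in the simulation of 1269 genes without any change, 39 of 42 draws with such a prior gave a call.

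By size alone, 15 genes were at least 2-fold apart with 1 sign on all 4 arrays, 7 higher and 8 lower, and none passed the test. Besides flgB, flgI, flhD, cheY (1.28 ± 0.20) and flgN (1.01 ± 0.25), the higher genes were yihV (1.19 ± 0.08) and the aldehyde dehydrogenase gene aldB (1.09 ± 0.03). The arrays of aldB differed by dye orientation, with 0.29 and 0.45 on the first arrays against 1.84 and 1.77 on the swapped ones. The lowest was aroF at -2.09 ± 1.30, which encodes the tyrosine-sensitive first enzyme of aromatic amino acid synthesis. It was followed by sulA (-1.58 ± 1.68), a cell division inhibitor of the SOS response, and leuB (-1.39 ± 0.80) of leucine synthesis. Malate synthase aceB lay at -1.34 ± 0.07, yjcH at -1.21 ± 0.29, iadA at -1.12 ± 0.94 and yfiL at -1.03 ± 0.76. Last came leuC, also of leucine synthesis, at -1.01 ± 0.53. The same rule applied to a sign pattern that follows the run gave 16 genes. Patterns that follow the dye or the run by dye gave 1 each. At 2-fold the strain count was therefore no larger than that of a contrast between runs. That contrast can itself hold strain differences of opposite sign in the 2 runs, so it is not a count of noise alone. The strain and run counts were 68 and 49 at 1.5-fold, 2 and 1 at 3-fold, and 13 and 12 at 2-fold after print-block centring. Leaving out 1 array gave 60 genes without 1-first, 17 without 1-swap, 41 without 2-first and 26 without 2-swap, with more genes measured in each case. Over the same 1269 genes the counts were 47, 17, 27 and 19. Patterns with a single array of opposite sign held 32 genes for 1-first, 0 for 1-swap and 7 each for 2-first and 2-swap, and 14, 0, 7 and 11 after print-block centring.

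**Figure D2:**
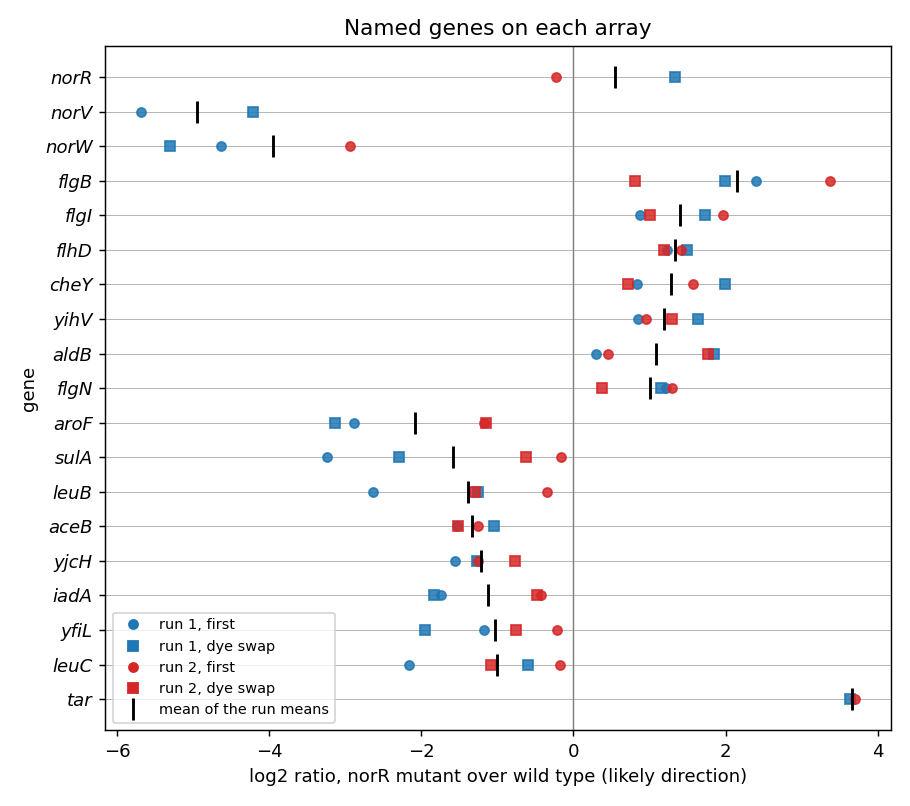
Log2 ratio (horizontal axis) of norR, norV, norW, the 15 genes at least 2-fold apart with 1 sign on all 4 arrays, and tar, on each array (points) and as the mean of the run means (black bars, for norV run 1 alone). Values of norV and norW lie between -5.69 and -2.93, and tar is at 3.63 and 3.70.

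None of the other 14 lists tested passed in the main setting. With an array left out 6 of them did at the preset correlation, as given below, and every such call was lost with an estimated correlation (adjusted p = 0.859 to 0.972), a setting with little power. Genes of the NsrR regulon, which responds to nitric oxide through a separate repressor, averaged -0.07 over 8 of 17 members (adjusted p = 0.639). Members yoaG and tehB were at 0.35 and -0.41. The list mean was -0.30 in run 1 and 0.16 in run 2, and 6 of the 8 changed sign between runs. One of them, hcr, was at -1.44 in run 1 and 1.72 in run 2. The genes hmp, hcp and ygbA lacked a value on some array and were left out. Iron uptake genes under Fur averaged 0.38 over 8 members (adjusted p = 0.218), with 0.87 in run 1 and -0.12 in run 2. They passed without 1-swap (0.43, adjusted p = 0.0273) and without 2-swap (0.60, adjusted p = 2.76e-05), not without 1-first or 2-first. In that list the siderophore synthesis gene entF was at 0.97 ± 0.21, and fhuF was at 2.36 in run 1 and -0.76 in run 2. Heat shock genes averaged 0.28 (adjusted p = 0.177; groL 0.57 ± 0.90, clpB 0.57 ± 0.23), from 0.60 in run 1 and -0.04 in run 2, and passed with print-block centring (adjusted p = 0.0434), a call lost there with an estimated correlation (adjusted p = 0.843). Their mean was 0.42 without 2-first, where they passed (adjusted p = 0.00419), and 0.08 without 2-swap (adjusted p = 0.767). Acid and RpoS stress genes averaged -0.25 (adjusted p = 0.121; otsA -0.56 ± 0.27). They passed without 1-swap (-0.37, adjusted p = 0.00791) and without 2-first (-0.26, adjusted p = 0.0233), not without 1-first (-0.18, adjusted p = 0.407) or 2-swap (-0.23, adjusted p = 0.195). SOS genes averaged -0.38 over 4 members (adjusted p = 0.300). The SOS mean was set largely by sulA, with sbmC at -0.74 ± 0.08 and dinI at 0.72 ± 0.91, and it was -0.06 over 14 members with the wider filter.

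Lists of anaerobic and central metabolism were near 0 on average, and in all of those below except the glycerol genes the 2 run means had opposite signs. Genes activated by Fnr, the anaerobic regulator, averaged 0.00 over 16 members (adjusted p = 0.836), and the nitrate reductase gene narG was at -2.10 in run 1 and 1.11 in run 2. Ribosomal protein genes averaged -0.44 in run 1 and 0.65 in run 2 (35 members, adjusted p = 0.662). They passed as higher without 1-first (0.28, adjusted p = 0.0371), and without 1-swap the mean was -0.08 (adjusted p = 0.0704). Aerobic respiration and TCA cycle genes averaged -0.11 (adjusted p = 0.300; gltA -0.94 ± 1.16), Fe-S cluster assembly -0.06 (adjusted p = 0.639; iscS -0.63 ± 0.54) and hydrogenase genes -0.02 (not past the threshold; hycD -0.57 ± 1.16, hybD 0.43 ± 0.33). Glycerol genes averaged 0.12 (adjusted p = 0.662; ugpC 0.71 ± 0.38, glpK -0.46 ± 1.21), methionine synthesis 0.16 (adjusted p = 0.552; mmuP 0.64 ± 0.01, metC -0.44 ± 0.89), arginine and pyrimidine synthesis 0.15 (adjusted p = 0.639; pyrI -0.80 ± 0.88, artQ 0.66 ± 0.14) and SoxRS and OxyR genes 0.07 (adjusted p = 0.836; zwf 0.36 ± 0.44). Methionine synthesis passed without 2-swap (0.56, adjusted p = 0.00287), while without 2-first its mean was -0.19 (adjusted p = 0.638). With print-block centring and the wider filter together it passed as well, as did heat shock (adjusted p = 0.00936 and 0.00619), calls lost with an estimated correlation (adjusted p = 0.879 and 0.883). The aerobic and TCA list passed without 1-swap (-0.24, adjusted p = 0.00714) and without 2-swap (-0.26, adjusted p = 0.0288). The mean and median differed in sign for the hydrogenase and SoxRS and OxyR lists, and the camera direction for the Fnr list was down while its mean and median lay just above 0; without centring the Fnr mean was -0.04. With the wider filter the glycerol mean was -0.04 and the SoxRS and OxyR mean -0.09. Leaving out 2-first gave a glycerol mean of 0.42 and an Fnr mean of 0.19. Leaving out 2-swap turned them to -0.28 and -0.24, and none of these passed. Of the chromosomal neighbours of norR, hypF alone had values on all 4 arrays (0.01 ± 0.24), too few for a list test.

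The 2 runs shared little across genes. Pearson's r between run means was -0.02 over 1269 genes (Spearman's rho -0.03), and 46.7% of genes had the same sign in both. Genes are not independent replicates, so no p is given. Without 1-first r was 0.38 and without 1-swap it was -0.36. The 2 arrays of a run also agreed weakly across features, and in run 1 not at all by rank. Pearson's r was 0.11 between 1-first and 1-swap and 0.26 between 2-first and 2-swap. Spearman's rho was -0.01 and 0.35, and 0.13 and 0.20 after print-block centring. The low agreement between runs therefore does not measure the cultures alone. The strain effect had an SD across genes of 0.38, the dye effect 0.34 and the difference between runs 0.39. The run-by-dye contrast, in which constant strain, dye and run effects cancel, had an SD of 0.31, so each of these SDs holds much noise.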

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

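All tests of explanations in this part were chosen after the results were seen. A single array stood apart from the other 3 by Dixon's criterion in 8 of 91 measures (array summaries, list means and named genes), where chance alone gives about 4.55. Of these, 4 were on 2-swap. Array 2-first held 2490 values against 3169 to 3308 on the others. On 2-swap the flagellar list mean was 0.47 against 1.41 to 1.46, flgN was 0.38 against 1.15 to 1.30, the methionine list mean was -0.93 against 0.43 to 0.69, and aspA was 2.25 against -0.33 to 0.08. On 1-swap the acid and RpoS stress list mean was 0.073 against -0.40 to -0.33. On 2-first sdhD was -1.33 against -0.36 to -0.22, and on 1-first wrbA was -0.72 against -0.33 to -0.25.

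Flagellar and chemotaxis genes were higher on average on all 4 arrays. Print-block bias is argued against by the list mean of 1.14 that stayed after print-block centring, and dye bias by a mean of 0.94 over the swapped arrays, the lower of the orientations. A strain difference in motility that has nothing to do with norR, such as a change elsewhere in the genome of one stock, cannot be told apart from an effect of norR, because both predict a higher list in both runs, and the lower run was at 0.96. An effect of the mutation therefore remains a hypothesis, and the same genes without nitric oxide were not analysed here.

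Array 1-first correlated negatively across features with both arrays of run 2 (Pearson's r -0.21 with 2-first and -0.29 with 2-swap), although 1-swap, made from the same run, correlated positively with them. The print-block medians of 1-first ran strongly opposite to those of 2-first (r -0.81) and 2-swap (r -0.93). Print-block bias accounts for part at most, since the correlations across features were still -0.12 and -0.20 after print-block centring. An unturned sign on 1-first is argued against by its flagellar mean of 1.43, a dye bias shared by the runs by the r of -0.21 between arrays of the same orientation, and a difference between the cultures of the runs by the lower r of 0.27 for 1-swap, which was 0.11 after print-block centring. The r of -0.21 and of 0.27 are part of the pattern that prompted the question, so they are no separate test of it. Features are not independent, so these correlations are less certain than their number implies. What is particular to the hybridisation of 1-first stays open, and no biological explanation beyond the cultures was tested.

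Methionine and iron uptake genes (16 on all 4 arrays) averaged 0.42 on 2-first and -0.66 on 2-swap, but 0.68 and 0.63 on the arrays of run 1. An unturned sign on 2-swap is argued against by the flagellar mean of 0.47 there, and print-block bias by a run 2 difference of 1.13 after print-block centring, against 1.08 before. A dye bias of the same size in both runs is argued against, since the difference was 0.048 (SE 0.17) in run 1 and the runs differed by 1.03 (SE 0.41). A shared bias that is weaker in run 1 cannot be told apart: the run 1 difference lay below the midpoint between 0 and the run 2 difference by 0.49 (SE 0.25), short of 2 standard errors. Both arrays of a run share their cultures, so no biological explanation was tested.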

How the results depend on the processing

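Print-block centring, alone or with the wider filter, an estimated correlation combined with either or with an array left out, camera on 4 arrays with an estimated correlation, and counts over the same genes with an array left out were chosen after seeing the data. The mean ratios of norR, norV and norW stayed within the spread between runs (arrays for norV) under every alternative that gave a value, with norR at -0.23 without run 1 or 1-swap. Leaving out 1 of 2 values, or 1 of the 2 runs, cannot move a mean by more than the SD of the 2. Those outcomes were therefore fixed in advance, and norR changed sign. The count of genes called was 0 in the main setting and in 10 of 12 alternatives that kept all arrays. It was 2 with the wider filter, 18 at an unadjusted p under 0.05 with at least 2-fold, and 0 to 11 with an array left out. The count of 2-fold genes, 15, was 68 at 1.5-fold, 2 at 3-fold and 17 to 131 with an array or run left out. The number of lists called, 1, was 4 with the wider filter, 2 with print-block centring, 6 with both, 2 to 4 with an array left out, and 0 with fry and in every setting with an estimated correlation. The p at the preset correlation measures spread over genes and not over the 2 runs. Fry and the estimated correlation had little power with so few residual degrees of freedom. The flagellar mean of 1.19 (1.14 with print-block centring) lost its call in those settings: adjusted p 0.780 with fry, and 0.917, 0.866 (4 arrays), 0.843 (print-block centring) and 0.879 (mean 1.07, with the wider filter too) with an estimated correlation. With an array also left out these were 0.972 (mean 1.03, 1-first), 0.859 (1.12, 1-swap), 0.949 (0.79, 2-first) and 0.764 (1.48, 2-swap). The correlation between runs was -0.36 to 0.38 with an array left out. The dye effect, 0.891 of the strain effect in SD, was 0.777 to 0.892 with a run left out. Over the same 1269 genes the 2-fold counts were 17 to 47 (47 without 1-first, 27 without 2-first). Looser thresholds raise counts by construction. Leaving out an array also loosens the 2-fold rule, because 1 sign is then needed on fewer arrays. In 32 genes of the 2-fold rule only 1-first had the opposite sign. For the other changes the cause was not tested. Leaving out a run gives values and no test. Among the 15 genes of 2-fold, 160 of 165 alternative values kept sign and side of the threshold, and 5 passed it. Among 57 other named genes, 594 of 627 did, 2 passed it and 31 changed sign without passing. For the 15 genes, keeping the sign was largely fixed in advance, because they were chosen for 1 sign on all 4 arrays. Leaving out the genes called singly moved nothing, as there were none. The small number of arrays, from 2 runs, limits the precision.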

Other observations

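With the wider filter of at least 1 array per run, 3 more lists passed in camera at the preset correlation, and all were lost with an estimated correlation (adjusted p = 0.823). The latter setting rests on few residual degrees of freedom and could hardly call any list. Iron uptake genes averaged 0.54 over 26 members (adjusted p = 9.45e-06), from 1.15 in run 1 and -0.06 in run 2, so the mean comes from run 1. The enterobactin genes entB and fes were at 2.42 and 2.25 in run 1, and at 0.07 and 0.30 in run 2, each from 1 array. These were the first arrays of both runs, so a dye bias would not cancel. With the wider filter, genes with 1 array in a run need not be balanced for dye. Acid and RpoS stress genes averaged -0.36 over 25 members (adjusted p = 0.000159), with -0.34 in run 1 and -0.38 in run 2. Of these, 10 were lower in both runs and 0 were higher in both. The acid resistance regulator gene gadE was at -0.87 ± 0.10 and the periplasmic chaperone gene hdeB at -1.07 ± 0.08. Aerobic respiration and TCA cycle genes averaged -0.22 over 32 members (adjusted p = 0.0190), from -0.07 in run 1 and -0.36 in run 2. Their array means were -0.20, 0.11, -0.71 and -0.0034 on 1-first, 1-swap, 2-first and 2-swap. Without 2-first, over the 24 members with the other 3 arrays, the mean was -0.0047 (adjusted p = 0.887).

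Other genes with large values, chosen after seeing them, did not pass in the main setting or with the wider filter. Of those named here, flgF passed without 2-swap (adjusted p = 5.67e-08), in a fit whose prior had infinite degrees of freedom. The flagellar rod genes flgC and flgF were at 2.45 ± 0.17 and 2.69 ± 0.87, and yeaR, a gene of the NsrR regulon, was at 2.03 on average over 1-swap and 2-first. The xanthosine transporter gene xapB was at -2.32 and the riboflavin synthesis gene ribB at -1.71. Of 52 features without a gene symbol and with values on all 4 arrays, 0 met the 2-fold rule.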
